A study of Homo sapiens with 12 samples.

How the data were processed

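RNA of LNCaP cells in 4 groups of 3 was labelled with biotin and hybridized to 12 Illumina HumanHT-12 V4 BeadChip arrays by the standard Illumina protocol, per the labels. The deposited table gives a signal intensity for each of 47323 probes on each array, neither background-subtracted nor normalized between arrays, as its values show. Beside it stands a detection p-value per the file headers, which moves in steps that give 770 negative control beads and is small where a probe lies above them. The authors also gave a processed table on the log2 scale with nearly equal medians on all arrays (6.187 to 6.217). Its normalization method is not given in the sources used here. Each of its 12 columns matched best the array of the same name in the signal table, with r of at least 0.957.

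The deposited signal was background-corrected with the normexp model of limma 3.58.1 (R 4.3.3), with the background read from the detection p-values and an offset of 16, then quantile normalized and put on the log2 scale. A probe was kept when its detection p was under 0.05 on at least 3 of the 12 arrays, which left 20413 probes. Of these, 15137 had exactly 1 gene symbol, and the probe with the highest mean log2 level stood for each gene, which gave 11517 genes. The 5274 kept probes without a symbol and the 2 with several were left out of gene counts. For 2894 genes more than 1 probe was kept, and 88 of the tested genes had kept probes called in opposite directions in at least 1 comparison, so text on a fold change of a named gene gives the other kept probes where they differ by more than 1 log2, a bound chosen after the values were seen.

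Precision is limited by the number of arrays. The median signal of an array lay between 93.84 and 107.2, and the median SD of a gene within a group was 0.105 log2 for vehicle, 0.112 for R1881, 0.105 for Torin 1 and 0.11 for both drugs. Within a group, arrays correlated with r of at least 0.9918. No pair of arrays held identical values. The arrays were grouped by the labels, and the replicate numbers were checked for pairing. After group means were removed, arrays of the same number correlated with a mean r of -0.00316 and those of different numbers with 0.00158, and 3 of 12 arrays correlated best with their own number, so the numbers were not used as a block.

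A single limma model with 4 group means was fitted to all 12 arrays, with 8 residual degrees of freedom and empirical Bayes moderation. Contrasts were R1881 against vehicle, Torin 1 against vehicle, both drugs against R1881, both drugs against Torin 1, both drugs against vehicle (count only), and the interaction, which is the R1881 response under Torin 1 less that without it. Adjusted p-values are limma's after Benjamini-Hochberg correction over all genes, and a gene is called under 0.05. Fold changes carry the SE of the model. Exact permutation of 3 arrays against 3 cannot give a two-sided p under 0.1, so no such test was run on single genes. Where a probe was detected on none of the 3 arrays of a group and on some of the other, the fold was computed against the lowest normalized level of any detected probe, array by array, and is given as at least that size. With detection on 1 or 2 of the 3 arrays of a group no bound was formed, and such folds rest in part on levels near the background.

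The comparisons, gene lists, the rule for named genes and the tests were chosen before the data were examined, except for the tests that the text says were chosen after the result was seen. There were 29 lists: androgen-induced genes, androgen-repressed genes, neuroendocrine markers, DNA replication and S phase, G2/M and mitosis, cholesterol synthesis, fatty acid synthesis, glycolysis, TCA cycle and pyruvate entry, oxidative phosphorylation subunits, serine, one-carbon and ATF4 amino acid genes, polyamine metabolism, ribosomal proteins, ribosome biogenesis, translation factors, lysosome, autophagy, FOXO targets and receptor feedback, mTOR complexes and regulators, unfolded protein response and ER folding (protein folding), hypoxia response, p53 targets, interferon response, coregulators and pioneer factors, luminal epithelial markers, basal prostate cell markers, stromal cell markers, immune cell markers, and stress and RNA quality genes. Each list with at least 5 measured genes was tested with camera at a preset correlation of 0.01, adjusted over 26 lists and 5 contrasts (130 tests). Camera with an estimated correlation and fry were alternatives. Members were also counted with p-values adjusted over the list alone.

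The named genes are the 10 largest rises and 10 largest falls among called genes whose 3 arrays in each group did not overlap, for R1881 and Torin 1 against vehicle and for both drugs against R1881. For both drugs against Torin 1 and for the interaction they are the 8 largest each way, without the overlap criterion in the interaction. Added to these are up to 4 members with the smallest adjusted p of each list that was called or had at least 1 in 3 of its members called, and KLK3, KLK2, TMPRSS2, FKBP5, MTOR, MYC, CCND1 and FASN in every comparison; other genes of this rule were not analysed here. Any list member may be named where its list is described, and genes with provisional names may be left out. The slope of the androgen response is a least squares slope through 0 across the genes called for R1881 against vehicle, and the pair of responses it compares shares no array. Overlaps of calls that share control arrays are given with the count expected of independent calls and with the mean over 100 simulations of unchanged groups.

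The alternatives were no background correction, median scaling or cyclic loess in place of quantile normalization, the authors' processed values, no detection filter or detection p under 0.01, the mean of a gene's probes, all kept probes, a fit of the compared groups only, the replicate number as a block, eBayes with trend and robust, array weights, leaving out each array in turn, and stricter thresholds. A range over the scalings covers the main fit, the first 3 of these alternatives and the authors' values, and is given for called list medians that one of them makes more than 1.5 times smaller. The procedure was tested on simulated data with 200 changed genes per contrast. Of changes of 0.5 log2 it recovered 73.1% for R1881 against vehicle and 25.4% for the interaction, and of changes of 1 log2 at least 97%. False calls made up between 1.96% and 7.46% of calls. In the simulated list test the shifted list was called and 0 of 25 others, and a simulated slope of 0.7 was recovered as 0.672. The simulated genes were drawn independently on the normalized log2 scale. The simulations therefore do not test correlation within lists, background correction or normalization.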

Results

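RNA levels were measured on 12 Illumina HumanHT-12 V4 expression arrays hybridized with RNA from LNCaP, a human prostate cancer cell line that responds to androgen. The cells were kept for 48 h without steroids and then treated for 48 h with R1881, a synthetic androgen (10 nM), with Torin 1, an inhibitor of both complexes of the kinase mTOR (100 nM), with both, or with the solvents alone (vehicle). Each of the 4 groups had 3 arrays, so n = 3 per group throughout. The stated interest of the series is how mTOR acting in the nucleus joins androgen signalling to gene expression. Between 16681 and 18868 of the 47323 probes were detected above background per array, with group means of 18307 ± 595 (SD) for vehicle, 17479 ± 556 for R1881, 18016 ± 885 for Torin 1 and 16895 ± 268 for both drugs. The first principal component held 49.9% of the variance and parted the arrays with R1881 from those without, and the second held 33.4% and parted the arrays with Torin 1 from those without. The labels do not say whether the 3 replicates were separate cultures, so the p-values describe the spread between these samples only.

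R1881 against vehicle asks what androgen did to gene expression in cells without Torin 1. The textbook androgen targets were far higher with R1881. TMPRSS2, a membrane serine protease, rose 14.0-fold (log2 3.80 ± 0.081, SE, adjusted p = 9.4e-13; probe ILMN_1791123). FKBP5, a co-chaperone of steroid receptors, rose 15.8-fold (log2 3.99 ± 0.097, adjusted p = 2.07e-12; probe ILMN_1778444). The kallikrein genes KLK3, which encodes prostate-specific antigen, and KLK2 were detected on none of the vehicle arrays and were at least 7.81-fold and at least 15.9-fold higher with R1881. The normalized log2 level of KLK3 was 4.47 ± 0.035 (SD, n = 3) with vehicle and 7.67 ± 0.284 with R1881. Among the other largest rises, GNMT, a glycine methyltransferase, rose 22.2-fold, NDRG1, a stress and differentiation gene, 20.2-fold, and TRIM51 20.9-fold. AGR2, a protein disulfide isomerase of the secretory pathway, rose 13.7-fold on its brightest probe, while its other kept probe gave a log2 change of 0.60. ORM1, an acute-phase plasma protein, was at least 12.2-fold higher and the tubulin gene TUBA3E at least 14.1-fold. Its near copy TUBA3D rose 13.8-fold, and its other kept probe, the brighter one without vehicle replicate 1, 2 or 3, gave a log2 change of 6.12. The largest falls were those of CAMK2N1, an inhibitor of CaM kinase II, 28.3-fold (log2 -4.82 ± 0.10, adjusted p = 9.4e-13), DDC, the decarboxylase that makes dopamine and serotonin, 20.3-fold, CBLN2, a synaptic organizer, 15.3-fold, and TGM3, a transglutaminase, 12-fold. OPRK1, the kappa opioid receptor, fell 10.1-fold, LRRN1 7.24-fold, GRB10, an adaptor of the insulin receptor, 6.72-fold (its 3 kept probes lay between -3.03 and -0.83 in log2), BCHE, butyrylcholinesterase, 6.3-fold and GASK1B 6.26-fold, and COLCA1 was at least 9.67-fold lower.

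As groups, 33 of 37 measured androgen-induced genes rose with R1881 and 2 fell (33 and 3 adjusted over the list alone), with a median log2 change of 2.23 and a camera adjusted p of 1.81e-33. Of 18 androgen-repressed genes, 14 fell and 2 rose (14 and 3 adjusted over the list alone), with a median of -1.09, or -0.89 with undetected members at their bounds, and a camera adjusted p of 5.2e-07 (median -1.12 to -0.573 over the scalings). UGT2B11, a glucuronosyltransferase that was placed in the repressed list, rose 6.96-fold (log2 1.79 on its other kept probe). Protein folding genes of the endoplasmic reticulum rose: 22 of 33 were up and 1 down, the same adjusted over the list alone, with a median of 0.49 (camera adjusted p = 2.11e-10). PDIA5, a disulfide isomerase, rose 3.38-fold and UAP1, which makes the sugar donor for N-glycans, 3.21-fold. In the hypoxia list 13 of 22 rose and 5 fell, also adjusted over the list alone, with a median of 0.58, or 0.42 with bounds (camera adjusted p = 0.000944; 0.183 to 0.663 over the scalings). ANKRD37 rose 7.73-fold and the circadian repressor BHLHE40 3.98-fold, and NDRG1 is a member of this list and of the androgen-induced list. These 4 lists kept their call when camera estimated the correlation between genes.

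Lipid synthesis genes were higher with R1881. Of 17 fatty acid synthesis genes 13 rose and 3 fell, and the same adjusted over the list alone (median 0.58, camera adjusted p = 5.76e-05, adjusted p = 0.065 with an estimated correlation). The elongase ELOVL5 rose 2.18-fold, the desaturase FADS1 1.67-fold and FASN, fatty acid synthase, 1.7-fold (log2 0.77 ± 0.089, adjusted p = 1.48e-05). Of 19 cholesterol synthesis genes 12 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.41, camera adjusted p = 0.000114, adjusted p = 0.0898 with an estimated correlation). EBP rose 1.83-fold and FDPS 1.64-fold, while TM7SF2, a sterol reductase, fell 1.77-fold. Polyamine genes rose, with 8 of 16 up and 1 down, the same adjusted over the list alone (median 0.36, 0.159 to 0.419 over the scalings, camera adjusted p = 0.001, adjusted p = 0.0869 with an estimated correlation). SAT1, which acetylates polyamines for export, rose 5.84-fold, SMS, spermine synthase, 5.09-fold and ODC1, ornithine decarboxylase, 3.02-fold. In glycolysis 8 of 21 rose and 2 fell, the same adjusted over the list alone (median 0.10, 0.0535 to 0.136 over the scalings, camera adjusted p = 0.0169, adjusted p = 0.0934 with an estimated correlation). The median was 0.191 without vehicle replicate 1 and 0.189 without R1881 replicate 3. The glucose transporter SLC2A3 was at least 8.85-fold higher, PFKFB2 rose 2.88-fold and hexokinase HK2 2.12-fold.

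Cell cycle genes were modestly lower with R1881. In the mitosis list 19 of 40 fell and none rose (22 adjusted over the list alone; median -0.25, -0.256 to -0.163 over the scalings, camera adjusted p = 0.000493, adjusted p = 0.0934 with an estimated correlation), among them TOP2A, a topoisomerase, 1.68-fold and PRC1, a spindle midzone protein, 1.55-fold. In the DNA replication list 13 of 38 fell and none rose, also adjusted over the list alone (median -0.25, -0.25 to -0.144 over the scalings, camera adjusted p = 0.00703, adjusted p = 0.199 with an estimated correlation), among them the helicase subunit MCM3 1.42-fold. Of 19 coregulators and pioneer factors 10 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.22, -0.232 to -0.128 over the scalings, camera adjusted p = 0.00605, adjusted p = 0.213 with an estimated correlation). The pioneer factor GATA2 fell 2.17-fold, the corepressor TLE3 1.88-fold and MYC 1.54-fold (log2 -0.62 ± 0.077, adjusted p = 2.74e-05), while GRHL2, a pioneer factor of epithelial enhancers, rose 2.05-fold. MTOR itself rose 1.85-fold (log2 0.89 ± 0.11, adjusted p = 3.73e-05; probe ILMN_1769031). Of 5 stromal cell markers 1 rose, ACTA2, smooth muscle actin, by 0.95 in log2, and none fell, also adjusted over the list alone (median -0.13, camera adjusted p = 0.875). For cyclin D1, CCND1, the log2 change was -0.23 ± 0.078 (adjusted p = 0.0306). That call was lost under 8 of 18 alternatives, with adjusted p between 0.0736 and 0.445, including those without vehicle replicate 2, vehicle replicate 3, R1881 replicate 1 or R1881 replicate 2, where it lay between 0.0736 and 0.122.

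In all, 4289 of 11517 genes differed between R1881 and vehicle, 1818 higher and 2471 lower, and 1460 of them by at least 1.5-fold. The 3 arrays of each group did not overlap for 5474 genes (47.5%), where chance gives 10%. With median scaling 2274 genes were higher and 2008 lower, so the larger share of falls rests on the scaling between arrays.

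**Figure D1:**
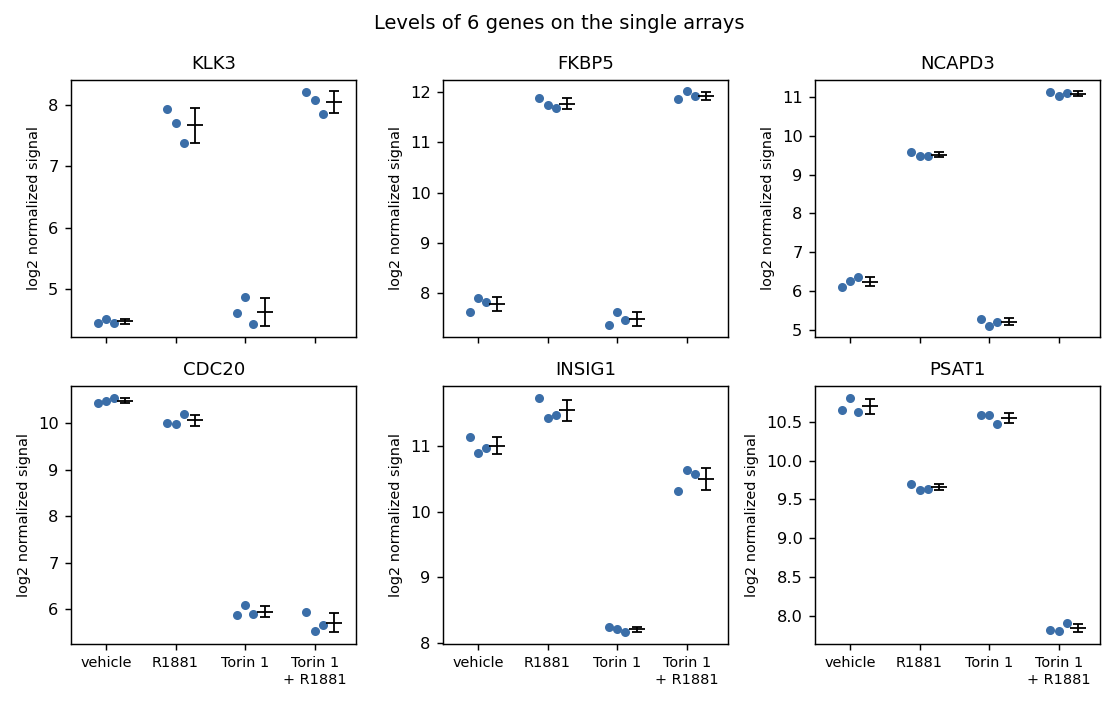
Normalized log2 signal of 6 genes in the 4 groups; points are the 3 single arrays of each group, and the bar beside them is the group mean with its SD. KLK3 stood at 4.47, 7.67, 4.63 and 8.05 with vehicle, R1881, Torin 1 and both drugs, and CDC20 at 10.48, 10.06, 5.95 and 5.71.

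Torin 1 against vehicle asks what mTOR inhibition did in steroid-deprived cells. The genes of cell division fell furthest. CDC20, an activator of the anaphase-promoting complex, fell 23.1-fold (log2 -4.53 ± 0.10, adjusted p = 2.1e-12), and TOP2A 15.8-fold (log2 -3.98 ± 0.078, adjusted p = 4.62e-13). UBE2C, the ubiquitin-conjugating enzyme of that complex, fell 25.6-fold on its brightest probe, and its other kept probe gave a log2 change of -0.53. DLGAP5, CDC45, BIRC5 and NCAPG were detected on none of the Torin 1 arrays and were at least 15.2-fold, 12.3-fold, 11.5-fold and 9.91-fold lower, but the other kept probe of BIRC5 gave a log2 change of -0.52. TK1, thymidine kinase, fell 13.6-fold, NUSAP1 11.3-fold and PTTG1, the securin, 11.1-fold. Rises were smaller. IGFBP3, which binds insulin-like growth factors, rose 4.16-fold (log2 2.06 ± 0.10, adjusted p = 5.84e-09), ID1, an inhibitor of helix-loop-helix factors, 3.73-fold on its brightest probe (log2 0.22 on the other), the synaptic adhesion gene NLGN1 2.94-fold, the lipid phosphatase PLPP3 2.72-fold and HS3ST1, a heparan sulfotransferase, 2.39-fold. MST1 rose 2.68-fold, ANKRD24 2.49-fold and the small nucleolar RNA SNORD3D 2.43-fold.

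In the mitosis list 39 of 40 genes fell with Torin 1 and none rose (40 adjusted over the list alone), with a median of -2.50, or -2.36 with 14 members at their bounds, and a camera adjusted p of 1.94e-55. The median lay between -2.58 and -1.17 over the scalings. In the DNA replication list 34 of 38 fell and none rose, the same adjusted over the list alone (median -1.29, or -1.26 with bounds, -1.33 to -0.787 over the scalings, camera adjusted p = 8.25e-31), with the flap endonuclease FEN1 5.11-fold lower and MCM10 at least 6.02-fold lower (log2 -1.08 on its other kept probe). Of 19 cholesterol synthesis genes 13 fell and 2 rose (14 and 2 adjusted over the list alone; median -1.02, camera adjusted p = 1.87e-10). INSIG1, the sterol sensor partner, fell 6.92-fold (log2 -2.79 ± 0.11, adjusted p = 2.47e-10; -1.24 on its other kept probe), HMGCS1 3.58-fold, EBP 3.49-fold and DHCR7 2.7-fold. In fatty acid synthesis 12 of 17 fell and 2 rose, the same adjusted over the list alone (median -0.55, camera adjusted p = 1.08e-06). The elongase ELOVL6 fell 3.19-fold, the desaturase SCD 2.6-fold and FASN 1.82-fold (log2 -0.87 ± 0.089, adjusted p = 8.72e-06). In glycolysis 9 of 21 fell and none rose (10 adjusted over the list alone; median -0.23, -0.28 to -0.148 over the scalings, camera adjusted p = 0.000493), with LDHA, lactate dehydrogenase, 1.76-fold and PGAM1 1.72-fold lower. These 5 lists kept their call with an estimated correlation.

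The lists of the TCA cycle and of oxidative phosphorylation had medians slightly below 0 with Torin 1. In the list of the TCA cycle and pyruvate entry 12 of 25 fell and none rose, also adjusted over the list alone (median -0.24, camera adjusted p = 0.00126, adjusted p = 0.1 with an estimated correlation), with IDH2 1.76-fold lower. Of 67 subunits of oxidative phosphorylation 19 fell and 1 rose (17 and 1 adjusted over the list alone; median -0.11, camera adjusted p = 0.00236, adjusted p = 0.377 with an estimated correlation). In the list of FOXO targets and receptor feedback genes, which insulin signalling represses, 16 of 29 rose and 3 fell (17 and 3 adjusted over the list alone; median 0.33, 0.205 to 0.354 over the scalings, camera adjusted p = 0.00134, adjusted p = 0.161 with an estimated correlation). TXNIP, a brake on glucose uptake, rose 2.14-fold, BCL6 2.08-fold and the insulin receptor substrate IRS2 1.8-fold, and SESN3 fell 2.12-fold.

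Of the androgen-induced genes 10 of 37 rose with Torin 1 and 8 fell (11 and 9 adjusted over the list alone), and the list was not called (median -0.01, camera adjusted p = 0.912). KLK4 rose 2.03-fold and ZBTB16 1.91-fold, while NCAPD3, a condensin II subunit, fell 2.04-fold (log2 -1.03 ± 0.084; probe ILMN_1683441) and CENPN, a centromere protein, 2.06-fold. The change was 0.16 ± 0.14 for KLK3 (adjusted p = 0.434), 0.23 ± 0.085 for KLK2 (adjusted p = 0.051), -0.08 ± 0.081 for TMPRSS2 (adjusted p = 0.505) and 0.00 ± 0.11 for MTOR (adjusted p = 0.997), all in log2. KLK3 and KLK2 were detected on 0 of 3 vehicle arrays and 1 of 3 Torin 1 arrays, so their values compare levels near the background and do not measure a change. FKBP5 was at -0.29 ± 0.097 (adjusted p = 0.0345). That call was lost under 6 of 18 alternatives (adjusted p 0.0584 to 0.125), including those without vehicle replicate 2, vehicle replicate 3, Torin 1 replicate 1 or Torin 1 replicate 3 (0.0865 to 0.125). The androgen-repressed list had 4 of 18 up and 5 down (4 and 6 adjusted over the list alone; median -0.14, camera adjusted p = 0.423). MYC rose 1.58-fold (log2 0.66 ± 0.077, adjusted p = 3.11e-05) and CCND1 fell 1.3-fold (log2 -0.38 ± 0.078, adjusted p = 0.00234). Beside these groups, 3 of 5 stromal cell markers rose and 1 fell, the same adjusted over the list alone (median 0.41, camera adjusted p = 0.182), with ACTA2 2.24-fold and VIM, vimentin, 1.34-fold higher. The fall, that of S100A4, was not called under 5 of 17 alternatives (adjusted p 0.0616 to 0.128), and the rise of TAGLN, transgelin, was not called without vehicle replicate 1 or Torin 1 replicate 2 or 3 (adjusted p 0.0605 to 0.0803). Torin 1 altered 3674 genes, 1869 up and 1805 down, and 926 by at least 1.5-fold. Median scaling gave 1691 up and 1851 down and cyclic loess 1642 and 2074, so the balance of rises and falls rests on the scaling between arrays. The groups did not overlap for 45.4% of genes, against 10% by chance.

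Torin 1 plus R1881 against R1881 asks what mTOR inhibition did in androgen-treated cells. Division genes fell again: CDC20 20.4-fold (log2 -4.35 ± 0.10, adjusted p = 3.53e-12), NUSAP1 12.9-fold (log2 -2.46 on its other kept probe), the kinase MELK 12.3-fold and the kinetochore gene SPC24 12-fold. DLGAP5 was at least 11.8-fold lower, CDC45 at least 9.82-fold, BIRC5 at least 9.45-fold (log2 -0.56 on its other kept probe), TK1 at least 9.08-fold and NCAPG at least 7.43-fold, and UBE2C fell 19.2-fold on its brightest probe (log2 -0.22 on the other). ID1 rose 7.61-fold (log2 2.93 ± 0.11, adjusted p = 1.71e-10; 0.60 on its other kept probe), IGFBP3 6.13-fold, IRS2 6.08-fold (log2 2.60 ± 0.094), HS3ST1 5.09-fold, NLGN1 4.61-fold and OTULINL 4.58-fold. NBL1, a BMP antagonist, rose 5.65-fold, ANGPT2, an angiopoietin, 5.51-fold, the growth factor MDK 4.77-fold and FBXO32, a ubiquitin ligase subunit that FOXO factors induce, 4.63-fold.

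In the mitosis list 39 of 40 fell and none rose (40 adjusted over the list alone; median -2.28, or -2.12 with 19 members at bounds, -2.28 to -0.995 over the scalings, camera adjusted p = 1.94e-36), and in the DNA replication list 34 of 38 (35 adjusted over the list alone; median -1.06, or -1.02 with bounds, -1.06 to -0.679 over the scalings, camera adjusted p = 7.88e-20). Androgen-induced genes were higher with Torin 1 added: 23 of 37 rose and 5 fell (24 and 6 adjusted over the list alone; median 0.44, camera adjusted p = 2.74e-05). PTGER4, a prostaglandin receptor, rose 3.01-fold, NCAPD3 2.97-fold, the metalloreductase STEAP4 2.76-fold and ZBTB16 2.69-fold (its 3 kept probes lay between 0.31 and 1.59 in log2). The log2 change of KLK2 was -0.21 ± 0.085 (adjusted p = 0.0645) and that of FKBP5 0.15 ± 0.097 (adjusted p = 0.231). KLK3 was at 0.38 ± 0.14 (adjusted p = 0.0452), a call lost under 7 of 18 alternatives (adjusted p 0.0554 to 0.199), including those without R1881 replicate 2 or 3 or replicate 1 or 2 of both drugs (0.0818 to 0.199; log2 0.23 without R1881 replicate 3). TMPRSS2 was at 0.25 ± 0.081 (adjusted p = 0.0212), a call lost without R1881 replicate 3 or replicate 2 or 3 of both drugs (adjusted p 0.0603 to 0.0775). The androgen-repressed list had 4 of 18 up and 4 down, the same adjusted over the list alone (median -0.07, camera adjusted p = 0.791).

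Amino acid and ribosome biogenesis genes fell in this comparison. Of 39 genes of serine and one-carbon metabolism and the ATF4 amino acid response 22 fell and 5 rose, also adjusted over the list alone (median -0.28, camera adjusted p = 0.000371). DDIT4, an mTORC1 inhibitor, fell 7.56-fold (log2 -2.92 ± 0.083, adjusted p = 1.94e-11), and the serine synthesis enzymes PSAT1 and PHGDH fell 3.52-fold (log2 -1.81 ± 0.075) and 2.78-fold. Of 38 ribosome biogenesis genes 29 fell and 2 rose, the same adjusted over the list alone (median -0.45, camera adjusted p = 4.85e-07), with NOP16 2.08-fold, RRS1 1.83-fold and BOP1 1.67-fold lower. In glycolysis 14 of 21 fell and 3 rose (16 and 3 adjusted over the list alone; median -0.67, camera adjusted p = 2.72e-05), with LDHA 3.67-fold (log2 -1.87 ± 0.070, adjusted p = 1.95e-10; its 3 kept probes lay between -1.87 and -0.78), PKM 2.05-fold and ENO1 1.88-fold lower. In the hypoxia list 12 of 22 fell and none rose (12 and 2 adjusted over the list alone; median -0.36, -0.364 to -0.21 over the scalings, camera adjusted p = 0.0018), with BHLHE40 6.43-fold and P4HA1 2.02-fold lower. The mitosis, DNA replication, androgen-induced, amino acid, ribosome biogenesis, glycolysis and hypoxia lists kept their call with an estimated correlation.

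Of 19 cholesterol synthesis genes 11 fell and 2 rose (12 and 2 adjusted over the list alone; median -0.50, -0.57 to -0.235 over the scalings, camera adjusted p = 0.00308, adjusted p = 0.161 with an estimated correlation), with EBP 2.74-fold, FDPS 2.37-fold and LSS 2.23-fold lower. In fatty acid synthesis 12 of 17 fell and 4 rose (13 and 4 adjusted over the list alone; median -0.67, camera adjusted p = 0.000182, adjusted p = 0.0828 with an estimated correlation), with ELOVL6 3.8-fold and FASN 1.76-fold lower (log2 -0.81 ± 0.089, adjusted p = 7.3e-06). For the TCA cycle 17 of 25 fell and 1 rose (18 and 1 adjusted over the list alone; median -0.30, camera adjusted p = 0.000722, adjusted p = 0.0899 with an estimated correlation), led by IDH1, 3.05-fold lower. For oxidative phosphorylation 28 of 67 fell and none rose, also adjusted over the list alone (median -0.22, camera adjusted p = 1.56e-05, adjusted p = 0.2 with an estimated correlation), with ATP5MC1 2.5-fold lower. FOXO targets rose, 16 of 29 up and 3 down, the same adjusted over the list alone (median 0.33, or 0.28 with bounds, 0.162 to 0.329 over the scalings, camera adjusted p = 0.00104, adjusted p = 0.158 with an estimated correlation). Protein folding genes rose as well, 15 of 33 up and none down, also adjusted over the list alone (median 0.22, camera adjusted p = 0.00366, adjusted p = 0.0637 with an estimated correlation), with the disulfide reductase DNAJC10 1.8-fold higher. MTOR rose 2.17-fold (log2 1.12 ± 0.11, adjusted p = 3.84e-06), CCND1 fell 1.7-fold (log2 -0.77 ± 0.078, adjusted p = 3.97e-06), and MYC was at 0.05 ± 0.077 in log2 (adjusted p = 0.662). Of the stromal markers 2 of 5 fell and none rose, the same adjusted over the list alone (median -0.12, or -0.02 with bounds, camera adjusted p = 0.28), with ACTA2 2.19-fold lower. The other fall, that of S100A4, was not called under 7 of 17 alternatives (adjusted p 0.0509 to 0.235). In this comparison 5234 genes differed, 2661 up and 2573 down (2418 and 2494 with median scaling), 1914 by at least 1.5-fold, and the groups did not overlap for 52.4% of genes (10% by chance). Of the genes called for Torin 1 with and without R1881, 2481 moved the same way and 118 in opposite ways.

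**Figure D2:**
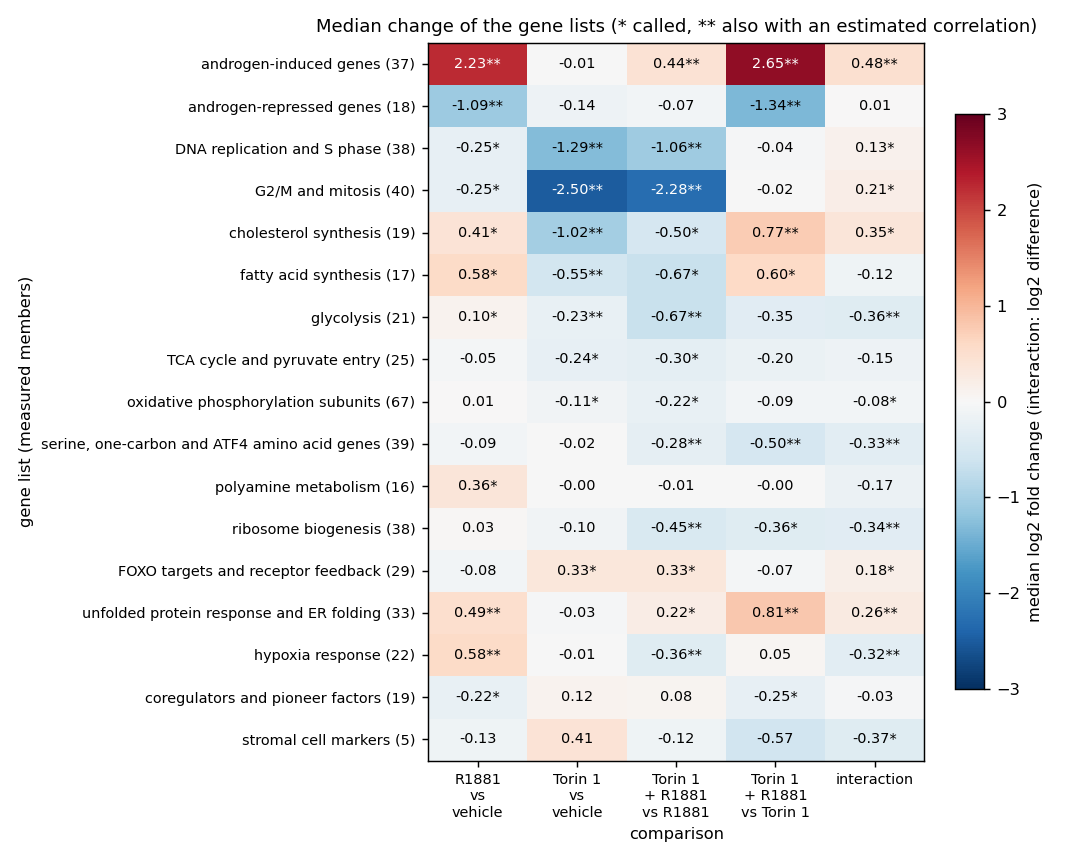
Median log2 fold change of the measured members of each gene list (vertical axis, number of members in parentheses) in the 4 comparisons and in the interaction (horizontal axis); 1 asterisk marks an adjusted camera p under 0.05 and a pair of asterisks a call that also held with an estimated correlation. The mitosis list stood at -2.50 and -2.28 in the comparisons for Torin 1, and the androgen-induced list at 2.23 and 2.65 in those for R1881.

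Torin 1 plus R1881 against Torin 1 asks how much of the androgen response stayed when mTOR was inhibited. The androgen targets rose here too: FKBP5 21.6-fold (log2 4.43 ± 0.097, adjusted p = 3.75e-13), TMPRSS2 17.5-fold, KLK2 14.9-fold (log2 3.90 ± 0.085) and KLK3 10.7-fold (log2 3.42 ± 0.14, adjusted p = 3.07e-10), the last 2 over levels detected on 1 of 3 Torin 1 arrays. TRIM51 rose 60.0-fold and NCAPD3 58.4-fold (log2 5.87 ± 0.084, adjusted p = 1.74e-14). NBL1 was at least 29.8-fold, ANGPT2 at least 23.1-fold, AGR2 at least 23.4-fold (log2 0.54 on its other kept probe) and HPGD, a prostaglandin dehydrogenase, at least 22.1-fold higher than with Torin 1 alone. TRIM48 and TRIM49D1 were at least 24.4-fold and 23.9-fold higher, and their probes belong to a family of near copies. DDC fell 24.2-fold (log2 -4.60 ± 0.11, adjusted p = 7.14e-13), CAMK2N1 17-fold, OPRK1 13.2-fold, CBLN2 12.1-fold, GASK1B 11.4-fold, BCHE 11-fold and LRRN1 9.63-fold, and COLCA1 was at least 7.69-fold lower.

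Of 37 androgen-induced genes 33 rose and 2 fell, the same adjusted over the list alone (median 2.65, camera adjusted p = 8.25e-31), and of 18 androgen-repressed genes 14 fell and 3 rose, also adjusted over the list alone (median -1.34, or -1.09 with bounds, -1.34 to -0.818 over the scalings, camera adjusted p = 6.4e-06). Protein folding genes rose, with 29 of 33 up and 1 down, the same adjusted over the list alone (median 0.81, camera adjusted p = 8.63e-14), among them PDIA5 4.56-fold and SDF2L1 2.48-fold. Cholesterol synthesis rose, with 15 of 19 up and 1 down (16 and 1 adjusted over the list alone; median 0.77, camera adjusted p = 6.44e-08), among them IDI1 5.08-fold, INSIG1 4.9-fold (log2 0.76 on its other kept probe) and SQLE, squalene epoxidase, 3.05-fold. Amino acid and ATF4 genes fell, with 25 of 39 down and 6 up (27 and 6 adjusted over the list alone; median -0.50, camera adjusted p = 4.07e-05). PSAT1 fell 6.54-fold (log2 -2.71 ± 0.075, adjusted p = 4.85e-12), the glycoprotein hormone STC2 4.49-fold and DDIT4 3.75-fold, while VLDLR, a lipoprotein receptor of the same list, rose 7.32-fold. These 5 lists kept their call with an estimated correlation.

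Fatty acid synthesis rose, with 10 of 17 up and 4 down, the same adjusted over the list alone (median 0.60, 0.227 to 0.644 over the scalings, camera adjusted p = 0.00473, adjusted p = 0.158 with an estimated correlation), and FASN was 1.76-fold higher (log2 0.82 ± 0.089, adjusted p = 5.38e-06). Ribosome biogenesis fell, with 26 of 38 down and 1 up (27 and 1 adjusted over the list alone; median -0.36, -0.358 to -0.228 over the scalings, camera adjusted p = 0.000844, adjusted p = 0.109 with an estimated correlation), among them BOP1 1.57-fold and dyskerin DKC1 1.56-fold. Of 19 coregulators 11 fell and 1 rose, also adjusted over the list alone (median -0.25, -0.252 to -0.148 over the scalings, camera adjusted p = 0.0372, adjusted p = 0.339 with an estimated correlation). That list's call was also lost with median scaling, cyclic loess and the stricter detection filter, without Torin 1 replicate 1 (adjusted p = 0.0501) and without replicate 2 of both drugs (adjusted p = 0.0586), within a range of 4.59e-05 to 0.339. MYC fell 2.35-fold (log2 -1.23 ± 0.077, adjusted p = 2.03e-08), CCND1 1.53-fold, and MTOR rose 4.03-fold (log2 2.01 ± 0.11, adjusted p = 7.26e-09). The cell cycle lists had no called shift: the mitosis list had 2 of 40 up and 3 down (1 and 3 adjusted over the list alone; median -0.02 with a sign that differed between scalings, camera adjusted p = 0.952) and the DNA replication list 7 of 38 up and 11 down (7 and 12 adjusted over the list alone; median -0.04, camera adjusted p = 0.875). Beside these groups, 3 of 5 stromal markers fell and none rose, the same adjusted over the list alone (median -0.57, camera adjusted p = 0.0652): ACTA2 2.54-fold, VIM 1.49-fold and TAGLN 1.48-fold. In all, 5191 genes differed, 2157 up and 3034 down, 2031 by at least 1.5-fold, and the groups did not overlap for 52.7% of genes (10% by chance). Median scaling gave 2456 up and 2348 down.

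Across the 4289 genes called for R1881 against vehicle, the androgen response under Torin 1 had a slope of 0.982 on the response without it, with r = 0.875, a relation across genes, which are not independent replicates. The slope lay between 0.963 and 0.992 when each array was left out in turn. It was 1.059 over the genes up with R1881 and 0.888 over those down. All of these genes were chosen by their response without Torin 1, and noise in that response favours a slope under 1. Of these genes 3813 (88.9%) kept their sign and 2892 (67.4%) were called in the same direction under Torin 1, while 115 were called in the opposite direction. Another 2184 genes were called for R1881 under Torin 1 and not without it. With both drugs against vehicle, 5853 genes differed, 2615 up and 3238 down, 2611 by at least 1.5-fold, and with median scaling 3138 were up and 2878 down.

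**Figure D3:**
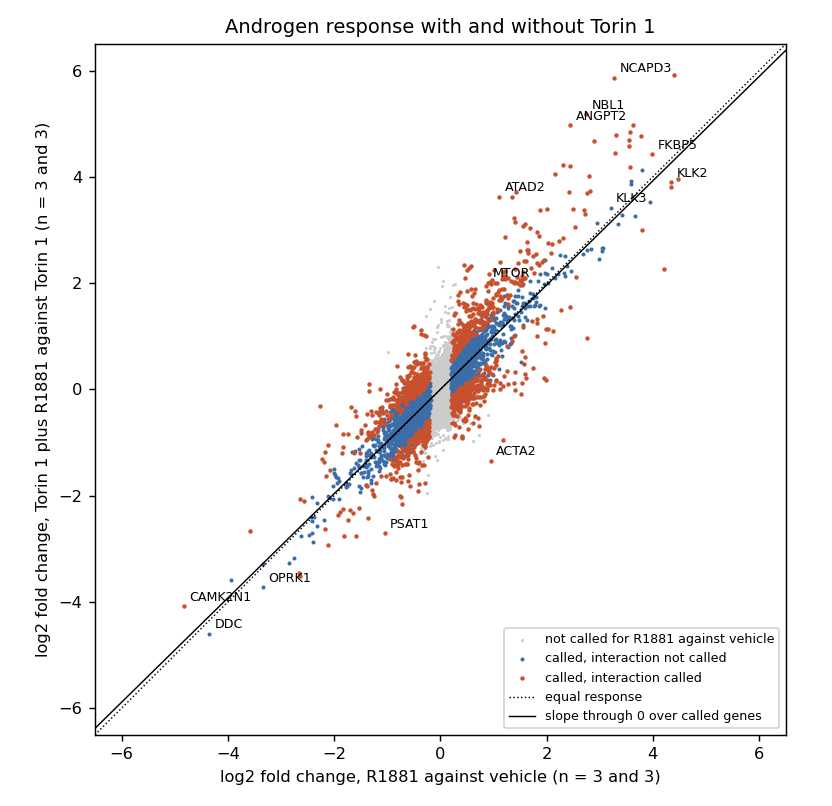
Log2 fold change of each gene for R1881 against vehicle (horizontal axis) and for Torin 1 plus R1881 against Torin 1 (vertical axis), n = 3 arrays per group; grey points were not called for R1881 against vehicle, blue points were, and orange points also had a called interaction. The dotted line marks equal responses, and the solid line has the slope of 0.982.

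The interaction tests whether the androgen response itself differed with Torin 1. The condensin gene NCAPD3 rose more under Torin 1, by 2.60 ± 0.12 in log2 (adjusted p = 6.13e-08), as did ATAD2, a bromodomain ATPase, by 2.52 ± 0.14, ANGPT2 by 2.53 ± 0.10 and NBL1 by 2.44 ± 0.14. CLDN8, a claudin, had an interaction of 2.29, the stress gene GADD45G of 2.27, and the kinase SGK1, detected on 1 of 3 Torin 1 arrays, of 1.93. CCN1, a matricellular protein, had a log2 response to R1881 of 0.05 (adjusted p = 0.734) without Torin 1 and rose by 2.04 with it, and TMSB15A, a thymosin, had -0.05 (adjusted p = 0.813) without it and rose by 2.30 with it. In the other direction, ACTA2 rose by 0.95 in log2 with R1881 alone and fell by 1.34 under Torin 1, an interaction of -2.29 ± 0.15 (adjusted p = 8.29e-07). PSAT1 fell by 1.05 without and by 2.71 with Torin 1 (interaction -1.66 ± 0.11, adjusted p = 8.29e-07). HBQ1, a theta globin, had an interaction of -1.69, and CRCP one of -2.12 ± 0.40 (adjusted p = 0.00321), with its 3 kept probes between -2.12 and -0.25. NNT, the mitochondrial transhydrogenase, and PNLIP, a pancreatic lipase, were detected on the arrays with R1881 alone and on none of the others, with interactions of -1.82 and -1.73. For MTOR the interaction was 1.12 ± 0.16 (adjusted p = 0.000532) and for MYC -0.61 ± 0.11 (adjusted p = 0.00234). It was 0.22 ± 0.20 for KLK3 (adjusted p = 0.535), 0.33 ± 0.11 for TMPRSS2 (adjusted p = 0.0709) and 0.05 ± 0.13 for FASN (adjusted p = 0.823). KLK2 was at -0.44 ± 0.12 (adjusted p = 0.0265), FKBP5 at 0.45 ± 0.14 (adjusted p = 0.0457) and CCND1 at -0.38 ± 0.11 (adjusted p = 0.0348). The interactions of KLK3 and KLK2 rest on levels at or near the background without R1881, and 0.23 of the size of that of KLK2 is the difference between those levels.

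The calls of KLK2, FKBP5 and CCND1 were lost under 8, 12 and 11 of 23 alternatives. KLK2 lost its call without vehicle replicate 2 or 3, R1881 replicate 1 or 3, Torin 1 replicate 3 or replicate 1 or 2 of both drugs (adjusted p 0.0513 to 0.0639), within a range over its alternatives of 0.00986 to 0.123. FKBP5 lost its call without vehicle replicate 2 or 3, R1881 replicate 2 or 3, Torin 1 replicate 1 or 3, or any 1 of the 3 replicates of both drugs (adjusted p 0.051 to 0.105, range 0.0113 to 0.105). CCND1 lost its call without vehicle replicate 1 or 3, R1881 replicate 3, any 1 of the 3 Torin 1 replicates, or replicate 1 or 2 of both drugs (adjusted p 0.0516 to 0.0809, range 0.00698 to 0.0809).

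Among the androgen-induced genes 20 of 37 had a positive and 5 a negative interaction (23 and 8 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 5.03e-06), among them CENPN at 1.89 and PTGER4 at 1.78. The androgen-repressed list had 2 of 18 up and 1 down, the same adjusted over the list alone (median 0.01, camera adjusted p = 0.912). Amino acid and ATF4 genes had a lower response under Torin 1, 18 of 39 down and 3 up (19 and 3 adjusted over the list alone; median -0.33, camera adjusted p = 5.47e-08), with DDIT4 at -1.49 and STC2 at -1.45, while VLDLR stood at 1.66. For ribosome biogenesis 14 of 38 were lower and 1 higher (21 and 1 adjusted over the list alone; median -0.34, camera adjusted p = 3.45e-08), with BOP1 at -0.68 and NOLC1 at -0.55. The glycolysis list had 8 of 21 lower and 2 higher (12 and 3 adjusted over the list alone; median -0.36, camera adjusted p = 0.000937), with LDHA at -1.06. In the hypoxia list 8 of 22 were lower and none higher (8 and 1 adjusted over the list alone; median -0.32, -0.325 to -0.156 over the scalings, camera adjusted p = 0.000577), with BHLHE40 at -0.85. Protein folding genes had 9 of 33 higher and none lower (13 adjusted over the list alone; median 0.26, camera adjusted p = 1.19e-05), with SEC24D at 0.72. The androgen-induced, amino acid, ribosome biogenesis, glycolysis, hypoxia and protein folding lists kept their call with an estimated correlation.

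For cholesterol synthesis 8 of 19 had a positive and 1 a negative interaction (11 and 2 adjusted over the list alone; median 0.35, 0.2 to 0.389 over the scalings, camera adjusted p = 2.09e-05, adjusted p = 0.065 with an estimated correlation), with IDI1 at 1.90 and SQLE at 1.25. For mitosis genes 6 of 40 were positive and none negative (9 adjusted over the list alone; median 0.21, camera adjusted p = 0.000371, adjusted p = 0.0906 with an estimated correlation), with PRC1 at 0.82. The 5 stromal markers had 2 negative, ACTA2 and VIM, and none positive, also adjusted over the list alone (median -0.37, -0.371 to -0.174 over the scalings, camera adjusted p = 0.0172, adjusted p = 0.0899 with an estimated correlation), a call that was also lost without the detection filter (median -0.0684, adjusted p = 0.116). Oxidative phosphorylation had 5 of 67 negative and none positive (4 adjusted over the list alone; median -0.08, -0.0835 to -0.0486 over the scalings, camera adjusted p = 0.0172, adjusted p = 0.497 with an estimated correlation), a call also lost with median scaling (adjusted p = 0.0528) and without vehicle replicate 2, R1881 replicate 2 or replicate 2 of both drugs (adjusted p 0.0574 to 0.0791, with a median of -0.051 without R1881 replicate 2). FOXO targets had 6 of 29 positive and 1 negative (6 and 2 adjusted over the list alone; median 0.18, camera adjusted p = 0.0334, adjusted p = 0.343 with an estimated correlation), with IRS2 at 1.75. That call was also lost with the stricter detection filter and with array weights, and without vehicle replicate 2, R1881 replicate 1, Torin 1 replicate 1 or replicates 2 or 3 of both drugs (adjusted p 0.064 to 0.0729). DNA replication had 6 of 38 positive and 3 negative (10 and 3 adjusted over the list alone; median 0.13, 0.0834 to 0.174 over the scalings, camera adjusted p = 0.0492, adjusted p = 0.339 with an estimated correlation), with FEN1 at 1.25. Its call was also lost with the stricter detection filter, with array weights and without vehicle replicate 2, R1881 replicate 1 or 2, Torin 1 replicate 1 or 2, or any 1 of the 3 replicates of both drugs (adjusted p 0.0578 to 0.118).

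Of the genes up with R1881, 294 rose more under Torin 1, 271 rose less or fell and 1253 had no called interaction. Of those down with R1881, 171 had a more negative response, 318 a less negative or a positive response and 1982 no called interaction. The interaction subtracts the same R1881 response that selected these genes. Noise in that response therefore favours a smaller response under Torin 1, and these splits do not measure a damping. In all 1721 genes had an interaction, 906 positive and 815 negative, 826 of them by at least 1.5-fold, and 667 of the 1721 were not called for R1881 against vehicle. Cyclic loess gave 1039 positive and 723 negative, so the near balance rests on the scaling between arrays. ANGPT2, NBL1, TUBA3E and TUBA3C (the last 2 at -1.93 and -1.79) were undetected in both groups without R1881. Their responses start from levels at the background, so their interactions come mainly from the difference between both drugs and R1881.

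The overlap of both drugs asks whether R1881 and Torin 1 moved the same genes. Against vehicle, 272 genes were up with both drugs taken singly (295 if calls were independent), 451 down with both (387), 432 up with R1881 and down with Torin 1 (285), and 664 down with R1881 and up with Torin 1 (401). When Torin 1 was added to R1881 instead, 491 genes rose with each (420 if independent), 495 fell with each (552), 641 rose with R1881 and fell with Torin 1 (406), and 935 fell with R1881 and rose with Torin 1 (571). Simulated groups without any change, sharing controls in the same way, gave a mean of at most 0.01 such genes over 100 simulations. Almost no gene is called when none changes, so that mean is low by construction. It does not show how shared arrays shape overlaps among genes that do change. Across genes, which are not independent replicates, the changes correlated with r = -0.02 for the pair that shares the vehicle arrays (0.499 in simulated unchanged groups) and -0.06 for the pair that shares the R1881 arrays (-0.498). The covariances were -0.00394 (0.00695 in simulated unchanged groups) and -0.0138 (-0.00695). Shared vehicle arrays push the changes in the same direction, so the opposed excess against vehicle does not come from them, while part of the excess of genes down with both may. Shared R1881 arrays push the changes apart, and as 3 arrays are too few to split, part of the opposed excess in that pair may come from them. INSIG1 and EBP, which rose with R1881 and fell with Torin 1, and TXNIP, which fell and rose, are among the opposed genes.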

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

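The test of scaling for the androgen-induced and ribosome biogenesis patterns and the test of S phase genes were chosen only after the result was seen.

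The androgen response differed between cells with and without Torin 1 in 1721 genes, by the interaction test. With R1881 labels reassigned among the arrays of each Torin 1 arm, 1 of 100 sets, the real one, gave as many genes, and the highest of the other sets gave 514. The other sets also break up the response to R1881 and so put it into the spread within groups, which keeps their counts low, so this relabelling does not test the interaction apart from the response.

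Androgen-induced genes responded more to R1881 under Torin 1, with a median interaction of 0.483 over 37 genes. The sign did not rest on the choice of scaling: the lowest median over the scalings and the authors' values was 0.33, with the call kept under each. All of these bring the arrays to a common level, so a shift of all genes together was not tested. Dim probes at the background stay open. The 26 members detected on all 12 arrays had a median of 0.464. Its 95% bootstrap interval, from resampled genes, was 0.0488 to 0.535 and reaches the bound of 0.1 set for that test. Genes are not independent replicates, so such intervals do not measure the spread between arrays. A stronger androgen response under mTOR inhibition is a candidate explanation that the design names and that was not tested apart from these.

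Ribosome biogenesis genes had a median interaction of -0.342, with a median change of 0.03 with R1881 alone (7 of 38 up and 3 down, the same adjusted over the list alone, camera adjusted p = 0.465) and a fall under Torin 1, whose call was lost with an estimated correlation (adjusted p = 0.109). The highest median change with R1881 under Torin 1 over the scalings and the authors' values was -0.228. The sign of the fall thus did not rest on the choice among these scalings, which all bring the arrays to a common level. A drop in the share of cycling cells stays open as a cause. The 28 S phase genes detected on all 3 Torin 1 arrays had a median change of -0.143. That was 0.214 above the -0.358 of the ribosome list. The interval of that gap, from resampled genes, was 0.0465 to 0.471 and positive throughout. The rule for that test also asked for a gap above the SD across the S phase genes, 0.508. That was not met, so the test does not decide. The whole DNA replication list was not called with R1881 under Torin 1 (median -0.036, camera adjusted p = 0.875). Single S phase genes went both ways, from -1.17 to 1.21. Lower MYC expression, or a direct effect of androgen on this program when mTOR is inhibited, may contribute and was not tested. MYC fell with R1881 under Torin 1, and its interaction was negative and called, as was that of the list. MYC also fell with R1881 alone, where the list was not called. Between both drugs and R1881, where the list fell, the difference in MYC was not called.

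Mitosis genes had a median interaction of 0.21, a call lost with an estimated correlation (adjusted p = 0.0906). Many of them lay near the background under Torin 1, where a further fall cannot be measured. The 16 members detected on all 12 arrays had a median of 0.192. Its 95% bootstrap interval from resampled genes, 0.0919 to 0.389, reaches the bound of 0.1, so this floor of the measurement stays open. The pattern and a smaller fall of these genes with R1881 where Torin 1 had already lowered them cannot be told apart here, because few members stay above background in all groups.

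The other lists with a called interaction had these median interactions: DNA replication and S phase 0.129, cholesterol synthesis 0.353, glycolysis -0.363, oxidative phosphorylation -0.083, amino acid and ATF4 genes -0.325, FOXO targets 0.183, protein folding 0.26, hypoxia response -0.321 and stromal markers -0.371. With an estimated correlation the calls of DNA replication, cholesterol synthesis, oxidative phosphorylation, FOXO targets and stromal markers were lost (adjusted p = 0.339, 0.065, 0.497, 0.343 and 0.0899).

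The genes with the largest positive interactions were NCAPD3 (2.601), ANGPT2 (2.526), ATAD2 (2.521), NBL1 (2.436), TMSB15A (2.357), CLDN8 (2.29), GADD45G (2.265) and CCN1 (1.988). Those with the largest negative interactions were ACTA2 (-2.288), CRCP (-2.124), TUBA3E (-1.932), NNT (-1.816), TUBA3C (-1.794), PNLIP (-1.725), HBQ1 (-1.694) and PSAT1 (-1.662). Of these 16 genes, ANGPT2, NBL1, TUBA3E, TUBA3C, NNT and PNLIP were undetected in both groups without R1881.

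Probes without a single gene symbol, which no gene count holds, also changed: of 5276 kept, 1006 were called for R1881 against vehicle (19.1%, against 33.6% of named probes), 937 for Torin 1 against vehicle (17.8% and 27.1%), 1444 for both drugs against R1881 (27.4% and 41.8%), 1307 for both drugs against Torin 1 (24.8% and 40.9%) and 305 in the interaction (5.78% and 11.7%). For R1881 against vehicle the largest rises were those of ILMN_1663787 (log2 5.25 ± 0.13, adjusted p = 3.23e-12) and ILMN_3279169 (log2 4.06 ± 0.076). For both drugs against Torin 1 these probes rose by 5.192 and 5.005 in log2. The largest fall was that of ILMN_1714730 (log2 -4.25 ± 0.11) for Torin 1 against vehicle.

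For the comparisons of 3 arrays against 3, the 10 possible splits are too few for a share under 0.05. The real counts and the highest of the other splits were 4289 and 0 for R1881 against vehicle, 3674 and 1 for Torin 1 against vehicle, 5234 and 0 for both drugs against R1881, 5191 and 0 for both drugs against Torin 1, and 5853 and 0 for both drugs against vehicle. The other splits mix arrays of both groups and so put the response into the spread within groups. Their low counts follow from that and lend no support to the real counts.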

How the results depend on the processing

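Of 477 results on named genes, 467 passed the threshold as reported and 446 of these passed it under every alternative run, and no called gene changed sign under a scaling. Most of these genes were named because they were called here, so these shares are high by selection. Sizes moved more: the noise-corrected SD of the R1881 response across genes without Torin 1 was 0.482 as reported. It was 0.317 without background correction and 0.352 with the authors' values. Over 8909 values, 8792 stayed on their side of the threshold, 104 fell out of the threshold, 12 entered it and 1 turned: ZMAT3 in both drugs against R1881 was at 0.188 as the mean of its probes, which disagree. Over 2612 values of 130 list medians, 2495 stayed on their side of the threshold, 52 lost and 63 gained a call and 2 turned with a call. Those were polyamine metabolism in both drugs against Torin 1, uncalled as reported, at 0.0123 with all kept probes (adjusted p = 0.046), and 0.0259 without Torin 1 replicate 1 (adjusted p = 0.0228), within -0.0415 to 0.035 over single arrays left out; the cause was not tested. Over the scalings and the authors' values, 20 of 78 uncalled medians and 0 of 52 called ones differed in sign, and 25 of the called ones were more than 1.5 times smaller at the weakest; their ranges are given where they are reported.

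The slope of 0.982 was 1.01 without background correction, 0.965 with median scaling, 0.968 with cyclic loess, 0.992 with the authors' values and with all kept probes, 0.993 over genes at adjusted p under 0.01, 1.01 over genes with at least 1.5-fold, and 0.963 to 0.992 without each array; the cause was not tested.

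Stricter thresholds gave fewer genes by construction. At adjusted p under 0.01, Torin 1 against vehicle had 2247 genes and the interaction 833. The overlaps were then 364 same and 553 opposite against vehicle, and 602 and 935 with Torin 1 added to R1881. With at least 1.5-fold the counts were 1460, 926, 1914, 2031, 826 and 2611 (R1881, Torin 1, both against R1881, both against Torin 1, interaction, both against vehicle), and the overlaps 82, 111, 194 and 273. Both drugs against vehicle gave 8800 with all kept probes, since more features were tested.

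Camera with an estimated correlation called 4, 5, 7, 5 and 6 lists in place of 11, 8, 13, 8 and 12. Fry, which does not compare a list with other genes, called 20, 20, 21 and 20 in the 4 comparisons and 16 in the interaction.

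With 1 array fewer, the 6 gene counts lay at 3642 to 3913, 2870 to 3212, 4652 to 4878, 4578 to 4771, 1359 to 1529 and 5300 to 5459, and the interaction called 8 to 12 lists, the 8 without vehicle replicate 2. With the replicate number as a block the counts were 4163, 3477, 5169, 5077, 1547 and 5783. A BeadChip block was not run, as the files name no chip. Signal over background limits the dim probes: 14 mitosis genes were undetected with Torin 1, so their falls are bounds.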

Other observations

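The test of the width of the androgen response was chosen only after the result was seen.

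Of the luminal markers, KRT8 rose 4.27-fold with R1881 alone (log2 2.09 ± 0.083) and 6.66-fold under Torin 1, and KRT18 rose 3.13-fold and 2.96-fold (log2 0.77 and 0.54 on its other kept probe). KRT19 was at least 1.93-fold higher with R1881 alone and was detected on none of the arrays with Torin 1 or with both drugs. CD24, a surface glycoprotein, fell 2.2-fold with R1881 alone (log2 -0.27 on its other kept probe). Of 13 luminal markers 4 rose and 4 fell with R1881 (5 and 4 adjusted over the list alone), and the list was not called (median 0.20, camera adjusted p = 0.295). Interferon response genes went both ways. The antigen presentation gene B2M rose 2.64-fold with R1881 and 4.06-fold under Torin 1 and the ubiquitin ligase HERC5 3.37-fold and 2.95-fold, while the antiviral GTPase MX1 fell 2.47-fold and 3.41-fold. With R1881 alone 6 of 27 rose and 8 fell, the same adjusted over the list alone (median -0.11, camera adjusted p = 0.983). In the lysosome list 10 of 42 rose and 15 fell with R1881, the same adjusted over the list alone (median -0.08, camera adjusted p = 0.675), with the cholesterol exporter NPC1 2.81-fold higher. With Torin 1, 6 rose and 13 fell, the same adjusted over the list alone (median -0.10, camera adjusted p = 0.295), with the galactosidase GLA 2.96-fold lower. In the autophagy list 8 of 37 rose and 8 fell with R1881, the same adjusted over the list alone (median 0.02, camera adjusted p = 0.407). WIPI1, which binds phagophore lipids, rose 3.62-fold, and TP53INP1 fell 4.33-fold. With both drugs against R1881, 15 rose and 4 fell, the same adjusted over the list alone (median 0.13, camera adjusted p = 0.0736), among them the initiating kinase ULK1, 1.68-fold higher.

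In the p53 list 10 of 19 fell and 2 rose with R1881, the same adjusted over the list alone (median -0.27, camera adjusted p = 0.0717), among them SESN1 by 3.21-fold, and 8 rose and 2 fell with Torin 1 (9 and 2 adjusted over the list alone; median 0.21, camera adjusted p = 0.0629). Of 30 genes of the mTOR complexes and their regulators 6 rose and 6 fell with R1881, the same adjusted over the list alone (median -0.05, camera adjusted p = 0.789), with TSC2 1.96-fold higher and DEPTOR, an inhibitor of mTOR, 1.77-fold lower. With Torin 1, 1 rose and 7 fell (0 and 7 adjusted over the list alone; median -0.07, camera adjusted p = 0.182). Translation factors had 3 of 38 up and 12 down with R1881, the same adjusted over the list alone (median -0.10, camera adjusted p = 0.402), with the kinase EEF2K 1.95-fold higher. With Torin 1, 7 were up and 8 down (8 and 8 adjusted over the list alone; median -0.01, camera adjusted p = 0.936). Ribosomal protein genes had 3 of 61 up and 9 down with R1881 (1 and 3 adjusted over the list alone; median -0.07, camera adjusted p = 0.451), and 10 up and 2 down with Torin 1 (8 and 2 adjusted over the list alone; median 0.06, camera adjusted p = 0.237). With both drugs against R1881, 13 were up and 5 down (9 and 5 adjusted over the list alone; median 0.07, camera adjusted p = 0.24). The stress list had 1 of 14 down and none up with R1881 (none adjusted over the list alone; median -0.03, camera adjusted p = 0.936), and 6 up and 1 down with R1881 under Torin 1, the same adjusted over the list alone (median 0.11, camera adjusted p = 0.222), where EGR1 rose 2.62-fold, FOS was at least 2.03-fold higher and JUN fell 1.75-fold. In glycolysis, R1881 under Torin 1 gave a median of -0.35 beside a mean of 0.07 and an uncalled downward test (4 of 21 up and 10 down, the same adjusted over the list alone, camera adjusted p = 0.613). For the lists called, median and test had the same sign. Among uncalled lists the median was below 0 while mean and test were above 0 for mTOR complexes (mean 0.04) and stromal markers (mean 0.09) with R1881, and for androgen-induced genes (mean 0.03) and translation factors (mean 0.02) with Torin 1. The same held for the TCA cycle with R1881, polyamine genes with Torin 1, polyamine and interferon genes with R1881 under Torin 1, and mTOR complexes and coregulators in the interaction. The median and the test also differed in sign for FOXO targets with R1881 under Torin 1, luminal markers in the interaction and stress genes with Torin 1.

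Lists with fewer than 5 measured genes were not tested. None of 2 basal prostate markers and none of 3 immune markers passed the test in any comparison adjusted over all genes, while 1 basal marker did with Torin 1 and 1 in the interaction adjusted over the list alone. Of 2 neuroendocrine markers, ENO2 fell 2.44-fold and TUBB3 1.49-fold with R1881, the same adjusted over the list alone. Of these lists, 10 of 12 basal, 13 of 16 immune and 16 of 18 neuroendocrine genes were not measured above background or had no annotated probe.

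Torin 1 may widen the androgen response across genes. With the noise of the estimates taken off, the SD of the log2 response across genes was 0.482 without and 0.581 with Torin 1, a ratio of 1.21, with 1.18 to 1.23 over the scalings and 1.19 to 1.22 without each array. Over the genes called under Torin 1, the slope of the response without Torin 1 on that with it was 0.683. Choosing genes by their response under Torin 1 favours a slope under 1 by itself, so this slope does not test the width. Over the genes called without Torin 1, the slope taken the other way was 0.982, and that choice of genes favours a slope under 1 in the same way.

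Genes next to each other on a chromosome might share an androgen response. Over 10844 neighbouring pairs of 11482 tested genes (GRCh38.p14 RefSeq order, pairs with the same first 3 letters left out), the rank correlation of the R1881 response was 0.133, with a one-sided permutation p of 1e-05, the smallest that 100000 shuffles of the gene order can give. The highest shuffled value was 0.0442. Of 1595 pairs with both genes called, 1032 (64.7%) moved the same way, against 51.1% by chance. For Torin 1 the correlation was 0.0162 (p = 0.046, highest shuffled 0.0393), and 597 of 1120 called pairs (53.3%) moved the same way, against 50% by chance. Adjusted over both tests, p was 2e-05 and 0.046. Paralogs with unlike names and probes that read into a neighbouring transcript were not removed.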
